A study of Homo sapiens with 6 samples.

How the data were processed

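RNA was measured in 6 libraries of cardiac tissue made from 253G1, an established human induced pluripotent stem cell line, whose cells the labels call cardiomyocytes. There were 3 libraries of tissue given ONO-1301, a synthetic prostacyclin agonist, and 3 of control tissue, all labelled day 3. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The labels do not say whether replicates came from separate cultures or differentiations, so the p-values measure only the spread between these samples, which may be technical.

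The deposited files give FPKM, fragments per kilobase of transcript scaled to the mapped fragments, which the authors computed before deposit, 1 value per gene symbol and library. Per the submitters' processing notes, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 were used with the human genome build hg19. The gene annotation, the filters and any scaling between libraries are not given in the sources used here. Groups were taken from the labels. The column headings of the control files carry an extra letter O that the ONO-1301 headings lack and that no label explains. If that letter stood for the compound, the groups would be exchanged and every direction would reverse, and nothing at hand settles this.

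The files list 26255 gene symbols, and 96 genes, which are XIST and the genes matched as Y-linked, were left out. Genes are named as the files give them, and no coordinates are printed because the annotation at hand was of another build than hg19. FPKM values are not counts, so no count model was used. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the values as deposited, unpaired and two-sided, with a variance trend. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 12525 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are ONO-1301 minus control on the log2(FPKM + 1) scale, which understates the change of low genes, while fold values are ratios of mean FPKM. An exact permutation test of a single value cannot go below 0.1 with 3 against 3 libraries, so no such test is reported. With 200 genes changed by 2-fold in simulated data of the same 12525 genes for this comparison, 85% were recovered with 1 false call, and at 4-fold 100% with 2 false calls. The simulated noise was independent between genes, and each gene took the median SD of genes of like abundance in its group. The spread of SDs between genes and the distance of ONO-1301 replicate 1 from replicates 2 and 3 were therefore absent. Recovery in the real data may be lower and false calls more frequent.

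Gene lists, 32 in all, the list test and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 28 of them, were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, a self-contained test, were run beside it. The named genes are the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, passing over small RNAs, unnamed transcripts, and XIST and Y-linked genes. To these were added up to 4 members past the threshold from each list that has such members or passes its test, or up to 2 members where a list that passes has no such member, and a fixed set of prostacyclin, paracrine, cardiomyocyte and reference genes. Other genes mentioned in the text are list members chosen after their values were seen. Some genes that the rule takes are not reported here.

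The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter and a mean FPKM of at least 5, rescaling by the median ratio or to equal sums, quantile normalization, no variance trend, robust variance moderation, a replicate block and leaving out each library in turn. Corrections for transcript length and GC content were added after seeing the data. Lengths were the median over a gene's transcripts in GENCODE release 29 and matched 11908 tested genes (95.1%). Their difference from the authors' annotation was not measured. A further fit with estimated library weights did not converge and was not used.

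Absolute sequencing depth is unknown from FPKM. Relative depth was read from genes with low values, under an FPKM of 0.15, whose ratios between libraries fall on multiples of 1 fragment's worth, to within 0.0015 on the natural log scale, using Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Among low genes whose step was fixed by the other 4 libraries, 89.4% and 86.7% of the matched values of ONO-1301 replicates 2 and 3 were whole rather than halved multiples of the step, to within 0.6%. Figures were drawn with matplotlib 3.10.9.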

Results

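Expression of 26255 genes was read in 6 libraries of cardiac tissue grown from human induced pluripotent stem cells, 3 with ONO-1301 and 3 control. ONO-1301 is a synthetic agonist of the prostacyclin receptor, and the series asks how its addition changes the transcripts of the cardiac tissue. The number of genes above an FPKM of 0 was 17914, 18421 and 18178 in ONO-1301 replicates 1 to 3 and 16889, 17470 and 17412 in the controls. Read from the steps of low FPKM values, the scaled depth of ONO-1301 replicates 2 and 3 was 0.411 and 0.439 of that of replicate 1. It was 0.98, 0.98 and 0.918 in control replicates 1 to 3. Absolute depth is unknown, and the lowest values of ONO-1301 replicates 2 and 3 rest on the fewest fragments.

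With ONO-1301 the tissue had more transcript from genes known to respond to low oxygen, led by NDRG1 and CA9. VEGFA and some other secreted vascular factors were higher, while FGF1 was lower. The tissue had less transcript from secreted liver-type proteins such as ALB and AFP. Transcript from the atrial-type myosin light chains MYL7 and MYL4 and other sarcomere genes was also lower. Several collagen genes, fibronectin and some other matrix genes were higher, and genes of cholesterol synthesis, cell division, oxidative phosphorylation and the ribosome were lower as lists. The list calls held with a preset correlation between genes and were lost with an estimated one, where the lowest adjusted p was 0.0786. Of 12525 tested genes, 1662 passed an adjusted p of 0.05 in limma, 434 higher and 1228 lower with ONO-1301, and 603 of them changed at least 2-fold. All 1662 had groups that did not overlap, as did 46.5% of all tested genes, against 10% by chance for a single gene. The genes share the same 6 libraries, so that share does not measure a departure from chance.

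The counts depended on the libraries and on scaling. Without ONO-1301 replicate 1 the count was 7812, without replicates 2 or 3 it was 217 or 32, and without control replicates 1, 2 or 3 it was 10, 18 or 15. Higher genes were 26.1% of the calls as deposited, 34.4% after median-ratio rescaling, 45.9% after quantile normalization and 95.5% after rescaling each library to the same FPKM sum, which raised the median change of all genes by 0.45 log2. Of 101 named genes past the threshold, 7 stayed past it in every alternative fit that tested them: NDRG1, PEG10, ALB, FABP1, AHSG, AMBP and FGL1. None of the 101 changed direction in any alternative, but their groups do not overlap, so leaving out a library could not reverse them. Over all calls, 9 of the 1649 tested after rescaling to equal sums changed sign. Groups follow the labels, but the control headings carry an unexplained letter O, and if it stood for the compound, every direction given here would reverse.

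The ONO-1301 libraries differed more among themselves than the controls did. The median SD of a tested gene on the log2 scale was 0.29 in ONO-1301 and 0.10 in control libraries. The first principal component held 66.9% of the variance and placed ONO-1301 replicate 1 at -12.3, replicates 2 and 3 at 65.7 and 49.3, and the controls between -35.2 and -32.9. Log2 changes rose with transcript length across 11908 genes (Spearman rho 0.371; genes are not independent replicates). Across the genes of each library, rho of its difference from the control mean with length was 0.165, 0.415 and 0.361 in ONO-1301 replicates 1 to 3. Median changes ran from -0.39 among transcripts of 841 to 1064 bases to 0.38 among those of at least 4512 bases. In ONO-1301 replicate 2 a single short RNA, MIR6087, held 40.2% of the FPKM sum and was listed at 0 in the other 5 libraries.

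**Figure D1:**
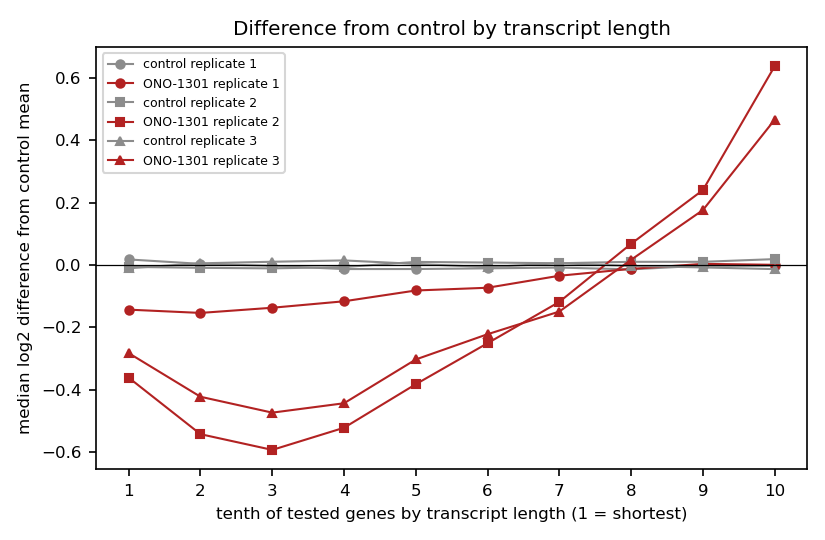
Median log2 difference of each library from the control mean (vertical axis) in 10 equal groups of the tested genes ordered by transcript length (horizontal axis), with ONO-1301 libraries in red and control libraries in grey. In the group of longest transcripts, replicates 2 and 3 with ONO-1301 lie at 0.64 and 0.47, and all the control libraries lie within 0.02 of 0.

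By camera with the preset correlation, the hypoxia list had the lowest p of the tested lists, while by fry the TGF-beta and YAP list was lower (adjusted p = 0.000955 against 0.0012). Of its 24 measured genes 15 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median log2 change of 1.18. Camera gave an adjusted p of 9.91e-14, and the adjusted p was 0.0786 with an estimated correlation. NDRG1, a stress-responsive gene, rose from 6.22 ± 0.36 to 65.4 ± 14.1 FPKM (SD, n = 3), a 10.5-fold rise with a log2 change of 3.18 ± 0.18 (SE) and an adjusted p of 0.000878. CA9, a carbonic anhydrase of the cell surface, rose from 0.882 ± 0.633 to 9.63 ± 3.31 FPKM. The hexokinase HK2 rose from 7.55 ± 0.417 to 40.6 ± 10.7 FPKM and the glucose transporter SLC2A1 3.22-fold. The transcription repressor BHLHE40 was 4.43-fold higher. Other hypoxia-regulated genes did not pass, such as PDK1 at 103 ± 11.7 against 96.6 ± 6.71 FPKM (adjusted p = 0.693). The list medians of the single ONO-1301 libraries were 1.06, 0.99 and 1.26 above the control mean, so replicate 1 was as far from the controls as the other 2 in these genes.

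Among the largest rises outside that list were the metallothioneins MT1F and MT1X, the neuron-type enolase ENO2 and PEG10, a gene derived from a retrotransposon. PEG10 rose from 10.6 ± 0.422 to 51.1 ± 2.51 FPKM and ENO2 from 37.3 ± 1.18 to 170 ± 25.4 FPKM. MT1X rose 5.77-fold and MT1F 10.1-fold, though metallothioneins have near-identical copies and their split is uncertain. The MT1F controls also spread widely, at 0.658, 1.46 and 3.83 FPKM, so the size of its rise is uncertain. ANGPTL4, a secreted lipase inhibitor, rose from 6.70 ± 1.15 to 30.1 ± 10.4 FPKM. NINJ2 rose from 1.75 ± 0.295 to 10.5 ± 4.04 FPKM. CDK8, CCNI and THBS1 were also among the 12 largest rises, but their ONO-1301 values spread widely: CDK8 was at 2.37, 16.7 and 11.6 FPKM against 0.738 ± 0.164 in the controls.

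**Figure D2:**
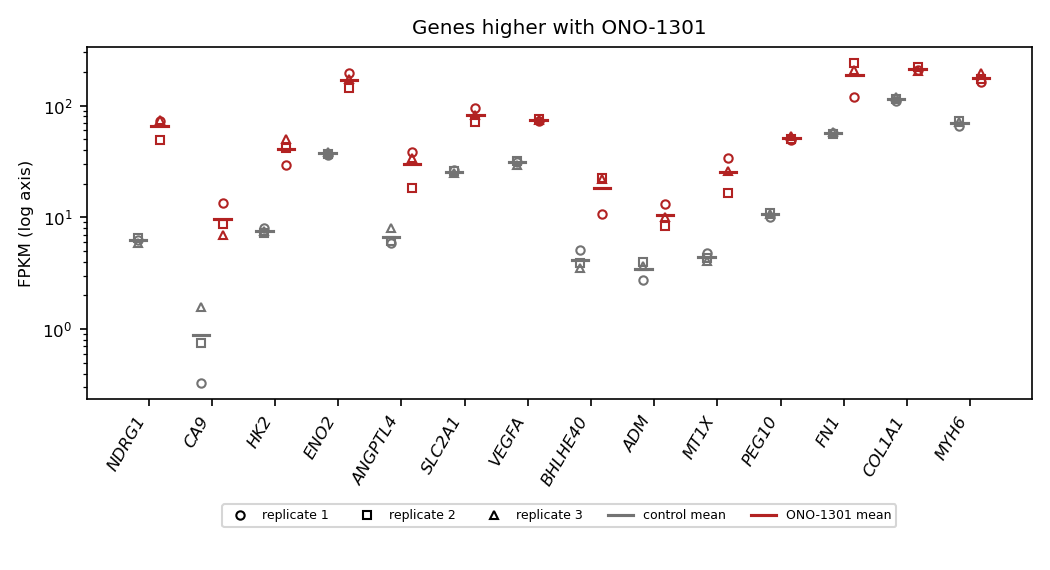
FPKM on a log axis of 14 genes past the threshold, with each library as a point (grey for control, red for ONO-1301, shapes for replicate numbers) and group means as bars. The ONO-1301 libraries lie above all the control libraries in each gene, with VEGFA at 74.1 against 31.0 FPKM.

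Angiogenic and paracrine factors rose as a list, with 5 of 19 genes higher and 1 lower (9 and 4 adjusted over the list alone), a median of 0.42 and an adjusted p of 0.011 (adjusted p = 0.307 with an estimated correlation). VEGFA, the main growth factor of blood vessels, rose from 31.0 ± 1.44 to 74.1 ± 2.18 FPKM, 2.39-fold, with an adjusted p of 0.00807. The vasoactive peptide APLN rose from 1.28 ± 0.267 to 5.14 ± 1.04 FPKM, and ADM and TGFB1 rose 3.01-fold and 2.38-fold. FGF1 was 2.45-fold lower. Members that did not pass went both ways. VEGFB, VEGFC and PGF lay lower, by 1.5-fold, 1.3-fold and 1.3-fold, and ANGPT1, PDGFB and TGFB2 higher, by 3.7-fold, 2.83-fold and 2.34-fold. VEGFA and ADM also belong to the hypoxia list. CXCL12, a chemokine, was at 5.47 ± 1.03 against 8.19 ± 0.453 FPKM and did not pass (adjusted p = 0.0576). HGF, a growth factor, lay under the filter at 0.121, 0.688 and 0.0789 FPKM with ONO-1301 and 0.537, 0.433 and 0 in the controls. FGF2 was between 0.501 and 0.698 FPKM in every library. Without ONO-1301 replicate 1 the list's adjusted p was 0.109. The list median was 0.25 after quantile normalization and 0.03 among the 13 members with a mean FPKM of at least 5.

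Genes that respond to cyclic AMP through CREB, the pathway that the prostacyclin receptor is known to feed, rose as a list. Of 19 measured genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median of 0.65 and an adjusted p of 2.26e-05 (adjusted p = 0.0786 with an estimated correlation). The nuclear receptor NR4A3 rose 3.36-fold and the immediate early genes FOS and JUNB rose 2.16-fold and 1.90-fold. CREM, whose products include a repressor of this response, fell 1.97-fold. The single ONO-1301 libraries had list medians of 0.42, 0.77 and 0.68, and the median was 0.29 without a filter and 0.39 without ONO-1301 replicate 2. Among prostanoid genes 2 of 6 were higher and 0 lower (2 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.332). Both were synthases: PTGES rose from 0.586 ± 0.157 to 3.28 ± 0.655 FPKM and PTGDS 3.08-fold. PTGIS, the prostacyclin synthase, was at 1.24 ± 0.196 against 0.886 ± 0.104 FPKM (adjusted p = 0.299). PTGIR, the prostacyclin receptor, was low, at 0.632, 0.203 and 0.114 FPKM with ONO-1301 and 0.288, 0.0509 and 0.0181 in the controls. The thromboxane synthase TBXAS1 and receptor TBXA2R were also under the filter, with TBXAS1 between 0.02 and 0.237 and TBXA2R between 0.459 and 1.47 FPKM.

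Liver-type genes made up most of the 12 largest falls. ALB, serum albumin, fell from 136 ± 20.4 to 10.9 ± 1.36 FPKM, 12.5-fold, with a log2 change of -3.52 ± 0.17 (SE) and an adjusted p of 0.000769. The fetal albumin AFP fell from 499 ± 61.6 to 86.1 ± 34.7 FPKM, and the apolipoproteins APOA2 and APOC3 fell 10.1-fold and 15.9-fold. APOC3 was at 3.92, 0.837 and 1.93 FPKM in ONO-1301 replicates 1 to 3, so the size of its fall depends on the library. FABP1, a fatty acid carrier of liver and gut, fell 10.2-fold. AHSG, AMBP, APOC2 and FGL1, other proteins that liver cells secrete, fell 9.03-fold, 4.63-fold, 5.60-fold and 26.7-fold. FGL1 lay near the floor with ONO-1301, at 0.351, 0.215 and 0 FPKM in replicates 1 to 3, so the size of its fall is uncertain. ORM1 was 8.77-fold lower, with reads that can be shared with its copy ORM2. Epithelial and endoderm markers fell as a list, with 6 of 11 genes lower and 1 higher (7 and 1 adjusted over the list alone), a median of -0.96 and an adjusted p of 0.00244 (adjusted p = 0.499 with an estimated correlation). Its lower members were mostly the liver-type genes, while the keratin KRT19 rose 1.89-fold. Single ONO-1301 libraries had medians of -0.66, -1.20 and -1.02. The list median shrank to -0.23 after quantile normalization (adjusted p = 0.022), to -0.42 after rescaling to equal sums and to -0.56 without a filter.

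**Figure D3:**
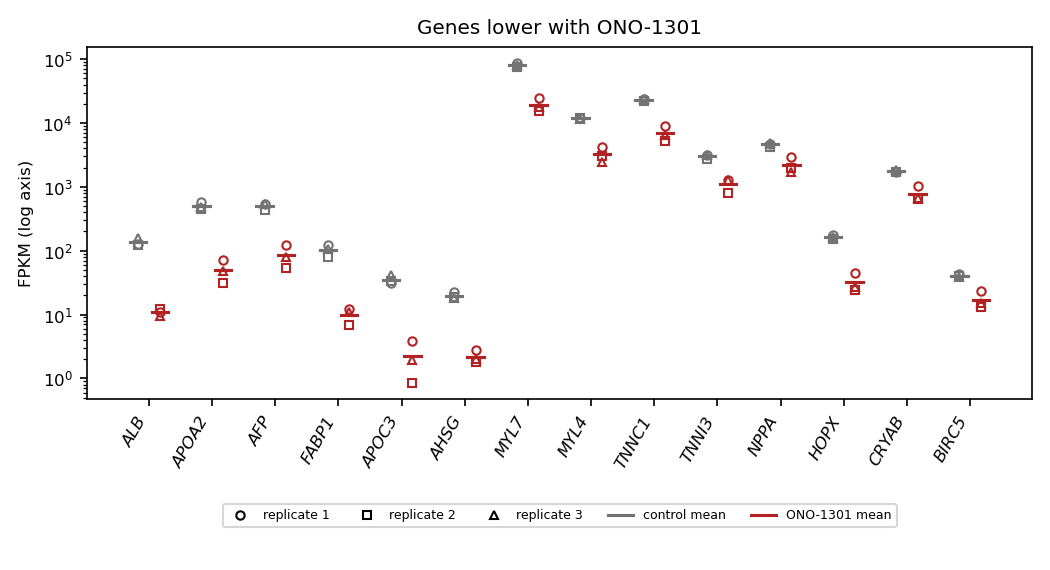
FPKM on a log axis of 14 genes past the threshold, drawn as in the plot of higher genes. The ONO-1301 libraries lie below all the control libraries in each gene, with ALB at 10.9 against 136 FPKM and MYL7 at 19380 against 81160 FPKM.

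Sarcomere genes fell as a list, with 13 of 22 genes lower and 1 higher (14 and 1 adjusted over the list alone), a median of -1.11 and an adjusted p of 0.00116 (adjusted p = 0.307 with an estimated correlation). MYL7, the atrial regulatory light chain and the most abundant control transcript, fell from 81160 ± 5887 to 19380 ± 5091 FPKM, 4.19-fold. The other atrial light chain MYL4 fell 3.63-fold, and the troponin subunits TNNC1 and TNNI3 fell 3.36-fold and 2.72-fold. MYH6, the alpha heavy chain, went the other way and rose from 70.3 ± 3.99 to 177 ± 16.5 FPKM (adjusted p = 0.00929). TTN, the giant spring protein titin, also lay higher on average without passing, at 175 ± 148 against 15.4 ± 1.46 FPKM (adjusted p = 0.142), with ONO-1301 replicate 1 below all the controls. MYH7, the near-identical neighbour of MYH6, was at 1775 ± 279 against 2492 ± 178 FPKM (adjusted p = 0.133), and reads shared between the pair make both uncertain. TNNT2 was at 7395 ± 1929 against 14710 ± 945 FPKM and did not pass (adjusted p = 0.058). The single ONO-1301 libraries had list medians of -0.77, -1.49 and -1.03. After quantile normalization the list median was -0.22 with an adjusted p of 0.148, and TNNT2 and MYH7 lay above the controls, MYH7 also after rescaling to equal sums.

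Calcium handling and ion channel genes had 3 of 18 members higher and 0 lower (3 and 0 adjusted over the list alone), with a median of 0.24 and an adjusted p of 0.0413 (adjusted p = 0.499 with an estimated correlation). They included the pacemaker channels HCN2, at 1.97 ± 0.258 against 0.485 ± 0.136 FPKM, and HCN4, at 4.86 ± 1.46 against 2.43 ± 0.189 FPKM. HCN2 was low in the controls, so the size of its 4.06-fold rise is uncertain. The list call was lost without ONO-1301 replicate 2 (adjusted p = 0.104) and with the length correction (adjusted p = 0.217). The list median of replicate 1 was -0.09. After quantile normalization the list median was 0.53. Cardiac transcription factors and natriuretic peptides had 0 of 15 higher and 2 lower (0 and 4 adjusted over the list alone) and did not pass (adjusted p = 0.591). The peptide NPPA fell from 4613 ± 366 to 2188 ± 629 FPKM and the ventricular factor IRX4 1.78-fold. Members that did not pass went both ways. TBX20 lay higher on average, at 36.7 ± 33.6 against 1.8 ± 0.4 FPKM (adjusted p = 0.0952). HAND1 lay lower, at 36.5 ± 14.3 against 65.6 ± 3.82 FPKM (adjusted p = 0.0579). NPPB was at 476 ± 113 against 589 ± 37.2 FPKM (adjusted p = 0.275), lying above the controls after quantile normalization and after rescaling to equal sums. HOPX, a cardiac homeodomain gene, fell from 163 ± 11.2 to 31.8 ± 10.8 FPKM.

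The extracellular matrix list rose, with 7 of 28 genes higher and 0 lower (13 and 1 adjusted over the list alone), a median of 0.53 and an adjusted p of 3.78e-05 (adjusted p = 0.0786 with an estimated correlation). Fibronectin, FN1, rose from 57.1 ± 1.13 to 189 ± 63.4 FPKM, and TNC, COL8A1 and COL4A1 rose 4.21-fold, 4.91-fold and 1.99-fold. Fibroblast markers had 5 of 14 higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.57 and an adjusted p of 0.0193 (adjusted p = 0.241 with an estimated correlation). The 5 were collagen genes, with COL1A1 rising from 116 ± 4.77 to 211 ± 10.1 FPKM and COL6A3 3.43-fold, while the proteoglycan gene LUM fell 1.64-fold. The fibroblast call was lost without a filter (adjusted p = 0.0946) and after rescaling to equal sums (adjusted p = 0.0545). TGF-beta and YAP targets had 7 of 19 higher and 1 lower (10 and 2 adjusted over the list alone), with a median of 0.52 and an adjusted p of 0.00116 (adjusted p = 0.118 with an estimated correlation). THBS1, a matrix glycoprotein, rose from 10.4 ± 1.23 to 52.7 ± 30.4 FPKM, while ID2 fell 2.66-fold. Medians of ONO-1301 replicates 1 to 3 were 0.32, 0.62 and 0.45 for the matrix list, 0.14, 0.68 and 0.71 for fibroblast markers and 0.48, 0.44 and 0.51 for TGF-beta and YAP targets. The other fibroblast markers did not pass and went both ways: POSTN, DDR2, PDGFRA and FAP lay higher, POSTN by 1.75-fold (adjusted p = 0.0584), and DCN, S100A4, THY1 and FBLN1 lay lower, S100A4 by 1.82-fold (adjusted p = 0.0691). Several of the genes that rose have long transcripts, and in the group of longest transcripts replicates 1 to 3 had medians of 0.00, 0.64 and 0.47, much as for the fibroblast list. After the length correction the medians were 0.45 for the matrix list and 0.47 for fibroblast markers, and both still passed (adjusted p = 0.000254 and 0.0168). The matrix median was 0.86 after quantile normalization.

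Endothelial markers had 1 of 8 higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.48 and an adjusted p of 0.0241 (adjusted p = 0.241 with an estimated correlation). The member was PLVAP, 1.91-fold higher, and the list's adjusted p was 0.13 without ONO-1301 replicate 1. The list median was 0.30 without a filter, and with a mean FPKM of at least 5 only 4 members were left, too few to test. Smooth muscle and pericyte markers moved in both directions, with NOTCH3 and PDGFRB higher and CNN1 and RGS5 lower among 11 measured (3 higher and 5 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.486). Few markers of other lineages were measurable: 2 of pluripotent cells, 4 of neural cells and 3 of leukocytes, too few to test as lists. Of these, TERF1, SOX3 and LYZ were lower, 1.56-fold, 6.76-fold and 3.17-fold (1, 1 and 2 genes lower and 0 higher adjusted over each list alone). SOX3 lay near the floor with ONO-1301, at 0.535, 0.326 and 0.0763 FPKM in replicates 1 to 3, so the size of its fall is uncertain.

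Energy metabolism differed between lists. Glycolysis genes had 2 of 20 higher, HK2 and SLC2A1, which also stand in the hypoxia list, and 1 lower (2 and 1 adjusted over the list alone), the muscle enzyme PGAM2 at 185 ± 49.8 against 510 ± 48.0 FPKM. The glycolysis median was 0.21 with an adjusted p of 0.0202 (adjusted p = 0.561 with an estimated correlation). It was lost without ONO-1301 replicate 1 (adjusted p = 0.202) and without a filter (adjusted p = 0.068), while after quantile normalization 14 of the 20 genes were higher, with a median of 0.94. Oxidative phosphorylation fell as a list, with 12 of 50 genes lower and 0 higher (43 and 0 adjusted over the list alone), a median of -0.91 and an adjusted p of 3.25e-08 (adjusted p = 0.542 with an estimated correlation). Among members past the threshold the largest falls were UQCRQ, ATP5J and ATP5G1, 2.52-fold, 2.27-fold and 2.19-fold. Cytosolic ribosomal protein genes fell as a list, with 2 of 42 lower, RPS9 and RPS23, and 0 higher (42 and 0 adjusted over the list alone), a median of -0.96 and an adjusted p of 1.17e-07 (adjusted p = 0.561 with an estimated correlation). Medians of single ONO-1301 libraries were -0.43, -1.39 and -0.93 for oxidative phosphorylation and -0.40, -1.45 and -0.97 for ribosomal proteins. After rescaling to equal sums, 0 members of either list passed alone, though both lists did, and after quantile normalization the ribosomal median was -0.01 (adjusted p = 0.942). The oxidative phosphorylation median shrank to -0.37 after rescaling to equal sums and to -0.22 after quantile normalization (adjusted p = 0.0089), with 2 members higher and 2 lower.

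Cholesterol synthesis fell as a list, with 8 of 19 genes lower and 0 higher (11 and 0 adjusted over the list alone), a median of -0.47 and an adjusted p of 0.00742 (adjusted p = 0.328 with an estimated correlation). EBP, FDPS and IDI1, enzymes of that pathway, fell 1.98-fold, 1.91-fold and 1.76-fold, and NSDHL was at 29.7 ± 8.45 against 62.3 ± 5.14 FPKM. After rescaling to equal sums the median was 0.00 and 0 members were lower, although the list test against other genes still gave a fall (adjusted p = 0.0483). Relative to the median of all genes, the list median was -0.36 as deposited and -0.33 after that rescaling. It was -0.24 after quantile normalization and -0.25 after the length correction, not set against other genes. The call was lost without ONO-1301 replicate 1 (adjusted p = 0.0704) and with a mean FPKM of at least 5 (adjusted p = 0.0783). Fatty acid oxidation had 1 of 23 higher, ANGPTL4, and 5 lower (1 and 8 adjusted over the list alone), among them the heart fatty acid carrier FABP3, 2.36-fold, and did not pass (adjusted p = 0.102).

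Cell cycle genes fell as a list, with 12 of 33 lower and 0 higher (19 and 0 adjusted over the list alone), a median of -0.59 and an adjusted p of 0.00484 (adjusted p = 0.499 with an estimated correlation). BIRC5, which acts in chromosome segregation and blocks cell death, fell from 40.7 ± 2.13 to 17.2 ± 5.38 FPKM, CDC20 2.08-fold and CCNB2 2.02-fold. Other members lay higher without passing, with TOP2A at 15.6 ± 7.76 against 8.43 ± 1.33 FPKM (adjusted p = 0.19) and CENPF, CENPE, MKI67 and TYMS 3.42-fold, 2.90-fold, 1.63-fold and 1.53-fold higher. Medians of single ONO-1301 libraries were -0.33, -0.48 and -0.73. The call was lost without ONO-1301 replicate 1 (adjusted p = 0.0609). After rescaling to equal sums the median was -0.07, or -0.40 relative to all genes, and after quantile normalization it was -0.37. Proapoptotic genes had 1 of 15 higher, BBC3, and 2 lower, CYCS and BIK (3 and 7 adjusted over the list alone). Antiapoptotic genes had 1 of 9 lower, BIRC5, and 0 higher (1 and 0 adjusted over the list alone). Neither list passed (adjusted p = 0.591 and 0.49).

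**Figure D4:**
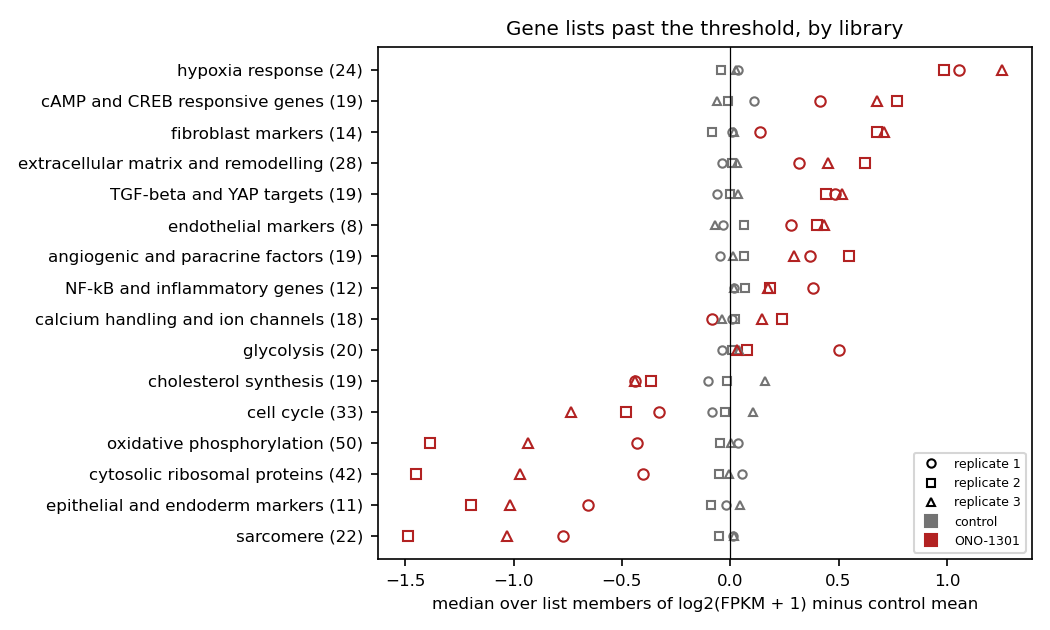
Median over the members of each list past the threshold of log2(FPKM + 1) minus the control mean (horizontal axis), with each library as a point, ONO-1301 in red and control in grey, and the number of measured genes in brackets. ONO-1301 libraries reach from -1.49 for sarcomere genes to 1.26 for hypoxia genes.

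NF-kB and inflammatory genes had 1 of 12 higher, IRF1, and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.25 and an adjusted p of 0.0246 (adjusted p = 0.241 with an estimated correlation). That call was lost without ONO-1301 replicate 1 (adjusted p = 0.161) and with a mean FPKM of at least 5 (adjusted p = 0.217), where the median of 6 members was -0.01. Heat shock proteins had 5 of 20 lower and 0 higher (8 and 0 adjusted over the list alone), including the muscle chaperones CRYAB, HSPB2 and HSPB3, each by over 2-fold, and did not pass (adjusted p = 0.102). HSPA1A, also lower, shares reads with HSPA1B. Interferon response had 2 of 9 lower, ISG15 and IFIT1, and 0 higher (3 and 0 adjusted over the list alone), and did not pass (adjusted p = 0.114). Oxidative stress genes had 2 higher, MT1X and MT2A, and 2 lower, GPX1 and GPX3, of 16 (2 and 2 adjusted over the list alone; adjusted p = 0.921). The unfolded protein list had TRIB3 and CHAC1 higher and SDF2L1 lower of 23 (3 and 2 adjusted over the list alone; adjusted p = 0.591). The p53 list had BBC3 and XPC higher and TP53I3 lower of 22 (2 and 1 adjusted over the list alone; adjusted p = 0.352). Replication-dependent histones had 1 of 15 lower, HIST2H2BE, and 0 higher (0 and 0 adjusted over the list alone; adjusted p = 0.49). No mitochondrial genome transcript was among the tested genes. The reference genes GAPDH, at 12710 ± 4117 against 11560 ± 241 FPKM, and ACTB, at 664 ± 200 against 783 ± 53.9 FPKM, did not pass (adjusted p = 0.844 and 0.423). ACTB lay above the controls after rescaling to equal sums and after quantile normalization, and GAPDH lay below them without ONO-1301 replicate 1.

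In total 16 of the 28 tested lists passed camera with the preset correlation, 10 higher and 6 lower, and 0 passed with an estimated correlation, the lowest adjusted p being 0.0786. Fry, which asks whether a list's genes move one way on balance, gave 16 lists past the threshold, but not the same ones. It did not pass ribosomal proteins, calcium handling or glycolysis (adjusted p = 0.0537, 0.121 and 0.127). It passed smooth muscle markers, interferon response and heat shock proteins instead, all lower (adjusted p = 0.0233, 0.0242 and 0.0119).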

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

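The length and GC corrections were chosen after seeing the data, as was the test on genes of known length. Genes past the threshold numbered 1662 as reported, and between 1540 and 2320 with other pseudocounts, a mean FPKM of at least 5, median-ratio rescaling, no variance trend, robust moderation, either correction or genes of known length. Without a filter the count was 255 (112 higher, 143 lower, 164 at least 2-fold), with 20270 genes tested. Rescaling to equal sums gave 2528 (2413 higher, 115 lower, 1114 at least 2-fold), and 9 of the 1649 calls tested there changed sign. Quantile normalization gave 771 (354 higher, 417 lower, 274 at least 2-fold), with 608 of the 1662 calls kept. As deposited, the FPKM sums were 1053760, 1085028 and 790352 in ONO-1301 replicates 1 to 3. They were 1442214, 1377369 and 1400310 in control replicates 1 to 3. Equal sums therefore raised ONO-1301 values against the controls, and the median shifted by 0.45 log2. MIR6087 held 40.2% of the sum of ONO-1301 replicate 2, so the rescaling of that library depends on it. The cause of the other differences was not tested. A mean FPKM of at least 5 gave 1918 lower genes. The length correction gave 712 higher genes and 392 genes at least 2-fold, and the length and GC correction 914 higher genes; the causes were not tested. Leaving out single libraries moved the count between 10 and 7812, higher genes between 2 and 2902, lower genes between 8 and 4910, and genes at least 2-fold between 10 and 2297. Fewer samples enter these fits, and the count rose only without ONO-1301 replicate 1, the library nearest to the controls.

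Gene lists past the threshold numbered 16 as reported, 0 with an estimated correlation and 10 to 16 when single libraries were left out, with 10 only without ONO-1301 replicate 1. They numbered 14 to 16 in the other alternatives, with lists exchanged in some of them. No filter lost fibroblast and glycolysis and gained fatty acid oxidation and heat shock, both lower (adjusted p = 0.00621 and 0.0133). A mean FPKM of at least 5 lost cholesterol, NF-kB and endothelial and gained p53, higher (adjusted p = 0.0437). Equal sums lost fibroblast and gained heat shock, lower (adjusted p = 0.0483). Quantile normalization lost sarcomere and ribosomal and gained p53 and unfolded protein, higher (adjusted p = 0.0255 and 0.00281). Leaving out ONO-1301 replicate 2 lost calcium handling and gained heat shock, lower (adjusted p = 0.0457), and both corrections lost calcium handling. The hypoxia list passed in each fit with the preset correlation. Of the 101 named genes past the threshold, 0 changed sign in any alternative, though leaving out a library could not reverse genes whose groups do not overlap. Those kept numbered 101 without ONO-1301 replicate 1, 42 and 15 without replicates 2 and 3, and 7, 9 and 10 without control replicates 1 to 3. Named genes that reversed had not passed as reported, and the cause was not tested. ACTB, at -0.28 log2, was at 0.26 after rescaling to equal sums, 0.48 after quantile normalization (adjusted p = 0.0311), 0.0034 after the length correction and 0.0086 after the length and GC correction. NPPB, at -0.33, was at 0.21, 0.40 (adjusted p = 0.0384) and 0.0195 after rescaling to equal sums, quantile normalization and the length and GC correction. MYH7, at -0.50, was at 0.042 after rescaling to equal sums and 0.36 after quantile normalization, where TNNT2 was at 0.0147. PTGIS, at 0.25, was at -0.12 after the length correction and -0.065 after the length and GC correction. GAPDH, at 0.09, lay between -0.16 without ONO-1301 replicate 1 and 0.24 without replicate 2.

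Replicate numbers gave no sign of pairing: correlations of same-numbered deviations from the group means were -0.02, 0.04 and -0.12. The libraries did not all correlate best with their own number. With 3 libraries per group these values cannot show that no culture or day was shared. A replicate block gave 297 genes (111 higher, 186 lower, 256 at least 2-fold), of which 287 were among the 1662. Depth limits the low genes: 1 fragment was worth 2.43 and 2.28 times as much FPKM in ONO-1301 replicates 2 and 3 as in replicate 1, so values near the filter are least precise there.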

Other observations

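The lists of metallothioneins and collagen hydroxylases, the tests on depth, on replicate 1, on quantile normalization and on equal loss of liver-type genes were chosen after results had been seen; the liver-type lists were written before their values were. Of 8 measured metallothioneins, metal-binding proteins, 4 were higher, MT1F, MT1X, MT2A and MT1G, and 1 lower, MT1L. MT2A rose from 27.8 ± 5.39 to 88.1 ± 21.5 FPKM (SD, n = 3), and MT1L was 4.42-fold lower. Reads shared among these near-identical genes leave the single members uncertain. Of 10 enzymes that modify collagen, 2 were higher, PLOD2, which hydroxylates lysine, 3.22-fold and P4HA1, which hydroxylates proline, 1.74-fold, and 0 lower. P4HA1 and P4HA2 also stand in the hypoxia list. No list test is given for these lists, because members already seen to rise prompted them.

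Of 12 measured hepatocyte genes outside the fixed lists, 10 were lower and 0 higher, with a median of -1.17 (camera p = 4.14e-06, p = 0.0509 with an estimated correlation). SERPINA1 fell from 204 ± 17.6 to 87.4 ± 34.7 FPKM and APOE from 557 ± 17.4 to 258 ± 50.8 FPKM, although APOE is also made by other cell types. The trend with the transcript lengths used is not the whole cause, since the median was -0.95 after the length correction. The 20 liver-type genes with a control mean of at least 5 FPKM did not fall by 1 factor: log2 changes with a pseudocount of 0.1 ran from -4.40 for FGL1 to -1.13 for APOE. Cochran's Q, which takes genes as independent, was 308 on 19 degrees of freedom. It was 189 on 12 without the 7 genes named for large falls outside these lists. The 13 genes left came from lists written before their values were seen. ALB, APOA2 and AFP among them were also among the 12 largest falls, and the others ran only from -2.16 for TM4SF4 to -1.13 for APOE. The spread rests largely on ALB, APOA2 and AFP. It cannot decide on a loss of 1 population, because genes that other cells also make, as with APOE, would then fall less. A smaller share of hepatocyte-like cells remains possible beside changes within cells, because only 3 of 10 hepatic transcription factors were measured, near the filter, with a median of 0.25, and these cannot be told apart here. A response to ONO-1301, the difference that the design names, stays open and was not tested apart from these.

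ONO-1301 replicates 2 and 3 lay apart from replicate 1. Lower depth alone is argued against, because both listed more genes above 0 (at least 18178) than any other library (at most 17914). Of 376 olfactory receptor genes, known mainly from the nose, 9.04% and 5.85% were above 0 in replicates 2 and 3 against at most 2.39% in any other library. Fragments spread over the genome, as from DNA or unspliced RNA, may contribute, but the genes are not replicates and no test of the samples was made. Whether replicate 1 responded less to the compound cannot be told: its median change was 0.886 of that in replicates 2 and 3 over all 24 measured hypoxia genes and 0.525 over the 325 genes of the 15 other lists past the threshold, but this sets 1 library against 2. RNA quality and culture differences stay open and were not tested.

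The lists with the clearest changes were set against trends over all genes. After the length correction the medians were 1.34 for hypoxia, -0.77 for epithelial and endoderm markers, -0.92 for sarcomere, -0.66 for oxidative phosphorylation and -0.67 for ribosomal proteins. All 5 lists still passed, so the trend with the lengths used is not their whole cause. Those lengths were medians over a gene's transcripts, such as 582 bases for NDRG1 and 569.5 for SLC2A1. Where they miss the expressed transcript, part of a length trend would stay uncorrected. After quantile normalization, which removes trends shared by genes of like abundance, hypoxia was at 1.36 and still past the threshold. Epithelial and endoderm markers, at -0.96 as deposited, were at -0.23, and oxidative phosphorylation, at -0.91, was at -0.22. Both still passed, but their medians shrank about as much as that of sarcomere genes. Sarcomere and ribosomal protein genes, at -1.11 and -0.96 as deposited, were at -0.22 and -0.0103 and no longer passed. The falls in all these lists may be wholly or partly a lower level of the most abundant transcripts in general. Members of the sarcomere and ribosomal lists are themselves abundant, though, and quantile normalization gives the top of every library the same values. It would also remove a fall particular to these genes, so it cannot tell these readings apart. For hypoxia genes, a response to ONO-1301, the difference that the design names, stays open, and no cause other than these trends was tested.

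Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 1662 genes, and the highest of the others gave 1. With 10 splits the share cannot fall under 0.05.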
